A study of Synechococcus elongatus PCC 7942 = FACHB-805 with 6 samples.

How the data were processed

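Each of 6 libraries came from cells of 1 strain at 1 time: RelA+ or RelAE335Q, before induction and 30 min and 1 h after 1.6 mM theophylline. Per the labels' protocols, cultures grew at 30 °C under 40 µmol photons per square metre per second, ribosomal RNA was depleted from total RNA, and libraries were made with a stranded kit and sequenced on an Illumina instrument. Bowtie 0.12.7 was used, per the submitters' processing notes. The genome build, the counting tool, its use of strand and the treatment of reads that map to several places are not given in the sources used here, so genes that overlap or have near-identical copies are uncertain.

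The authors deposited 1 table with 2715 gene IDs and a value per library in RPM (reads of a gene as a share of the library's reads), a unit read from the values. Within a tolerance of 1e-05, 100% of the values in each library were a whole number of reads times the RPM scale over 1 whole-number denominator, with no division by gene length. The denominators were 7892594, 10925269 and 12424933 reads for RelA+ at 0 min, 30 min and 1 h, and 13886321, 11350650 and 10510836 reads for RelAE335Q. The listed IDs held 5870894, 8439936 and 9005653 of the RelA+ reads and 10955311, 9145764 and 8068541 of the RelAE335Q reads, so 19.4% to 27.5% of the denominator lay outside them. The share outside was higher in RelA+ than in RelAE335Q at each time. It was 25.6% against 21.1% at 0 min, 22.7% against 19.4% at 30 min and 27.5% against 23.2% at 1 h. One read was worth 0.0720 to 0.127 RPM. A value of 0 allows up to 3 reads, or 0.216 to 0.380 RPM, and 13 to 21 IDs per library were at 0. Because RPM is a share of all reads, a change in the share of a few abundant RNAs, or of reads outside the listed IDs, moves every other gene.

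The file does not pair its IDs with gene names, and none of the IDs matched the 2785 genes of the reference table used here (assembly ASM3054490v1; 0 matches). Of 28 gene lists fixed before the data were examined, 27 were defined by names or products and had no members, and are not analysed here. The circadian clock list had 6 members by locus tag. The tags of 8 loci (the 6 clock genes, rel and hpf) were also fixed beforehand, from general knowledge. IDs fell into 53 with an R in their number (32 tested), 50 with a B (19 tested) and 2612 others; what R and B stand for is not stated in the file.

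Values were taken as log2(RPM + 1), so folds of low genes are understated. IDs with a mean over the 6 libraries above the 10th percentile of all IDs, 9.31 RPM, were kept, which left 2443. With 1 library per group, no test of a strain difference at a single time or of the difference of changes was possible, and no p-value was computed. A model with strain and time as additive terms, which would average the strain difference over all 3 times with the one before induction included, was not run. Comparisons were RelA+ over RelAE335Q at each of 3 times, each later time over 0 min within each strain, and the difference of these changes between strains, 9 in all. The summary is the number of IDs at least 2-fold apart. For single genes the ratio of recovered reads was given with a 95% counting interval, from the exact (Clopper-Pearson) binomial interval of a pair of libraries, or a normal approximation for a difference of changes. These intervals cover counting error only. Poisson draws (100) gave the number of 2-fold differences from counting error alone. The median of a list was placed among 10000 random lists of the same size matched in 10 bins of mean expression. Overlaps of lists are set beside the overlap of independent lists; comparisons set side by side in this way share no library. The correlation intervals come from 1000 bootstrap draws over genes.

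The rule for named genes ranked IDs by the smaller absolute value of RelA+ over RelAE335Q at 1 h and the difference of changes at 1 h, where both had the same sign. Without names, its limit for unnamed genes applied, and the 2 leading IDs each way are given. The parts of the rule that ask for named genes at 0 min, at 30 min and in RelAE335Q were not applied for the same reason, and genes of the fixed list of always reported genes without a tag are not analysed here. The plan left ribosomal and transfer RNA rows out of equal totals; since the file does not mark such rows, the R-numbered IDs were left out in their place.

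Alternatives were median-of-ratios scaling, equal totals without the R-numbered IDs, quantile normalization, no filter, a filter at the 25th percentile, pseudocounts of 0.1 and 10, the 99th percentile of the absolute fold at 0 min as the threshold (2.19-fold), 30 min in place of 1 h and, for lists, the mean. Those added after the data were seen were the R-numbered and B-numbered IDs as lists, leaving out the R-numbered IDs, and thinning all libraries to 7892594 reads. The code was tested on simulated data for RelA+ over RelAE335Q at 1 h, with 200 of 2443 genes changed 4-fold: it recovered 100% of the 100 higher and 100% of the 100 lower genes and called 0 unchanged genes. The simulated libraries differed by counting error alone, apart from the planted changes. The outcome therefore checks the code and gives no rate of false calls between cultures. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.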

Results

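Messenger RNA levels were measured in Synechococcus elongatus PCC 7942, a unicellular cyanobacterium with a circadian clock, in a pair of strains that carried an inducible copy of relA in a wild-type background. RelA synthesises the alarmone (p)ppGpp, the signal of the bacterial stringent response. One strain carried the active enzyme (RelA+) and the other the E335Q variant (RelAE335Q), known as a form without synthetase activity. Cultures entrained by 12 h phases of light and dark were released into constant light, and 1.6 mM theophylline, the inducer, was added at subjective dusk (12 h of circadian time). Cells were taken before induction (0 min), at 30 min and at 1 h, which gives 6 groups with 1 library each. No group had a replicate, so no difference below has a replicate check and none has a p-value. The 95% intervals given for single genes cover counting error only.

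The libraries held 7892594, 10925269 and 12424933 reads in the RelA+ strain at 0 min, 30 min and 1 h, and 13886321, 11350650 and 10510836 reads in the RelAE335Q strain. Of these, 5870894 to 10955311 reads per library fell in the 2715 listed gene IDs, of which 2443 passed the filter on low values. The median ID stood at 62.8, 50.5 and 44.7 RPM (reads scaled to a common library total, not to gene length) in the RelA+ strain and at 64.5, 61.9 and 52.6 RPM in the RelAE335Q strain. A single ID, Synpcc7942_R0017, chosen for mention after its values were seen, took 21.2%, 24.98% and 25.4% of all reads in the RelA+ libraries at 0 min, 30 min and 1 h, against 21.4%, 22.3% and 25.2% in the RelAE335Q libraries.

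The main comparison set the active against the inactive enzyme 1 h after induction. More genes were lower than higher with the active enzyme: 99 IDs were at least 2-fold lower and 2 at least 2-fold higher in RelA+ than in RelAE335Q. Of the 99 lower IDs, 11 carried an R in their number, a class of IDs whose meaning the file does not state. The file gives IDs without gene names, so the leading genes can be given by ID alone. Synpcc7942_0891 stood at 5.31 RPM in RelA+ and 57.9 RPM in RelAE335Q at 1 h, 9.34-fold lower (log2 -3.22, or -2.15 with a pseudocount of 10). The interval of its log2 ratio without a pseudocount was -3.84 to -3.08. Before induction it stood at 24.20 and 23.04 RPM in the same order. The leading IDs were ranked on the difference of changes at 1 h as well. That passes over IDs that already differed the same way before induction, so their starting levels are no separate check. Synpcc7942_2300 was 5.62-fold lower at 1 h, at 33.8 against 195 RPM (log2 -2.49, interval of the ratio -2.68 to -2.37).

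Synpcc7942_2529, one of the 2 higher IDs, reached 4329.8 RPM in RelA+ and 1958 RPM in RelAE335Q at 1 h, a log2 fold of 1.14 (interval 1.12 to 1.17). Its level was 848 RPM in RelA+ and 1068 RPM in RelAE335Q before induction and was higher after induction in both strains. The log2 change from 0 min to 1 h was 2.35 with the active enzyme and 0.87 with the inactive one. Synpcc7942_0746 was at 13.3 RPM in RelA+ and 6.56 RPM in RelAE335Q at 1 h, a log2 fold of 0.92, or 0.49 with a pseudocount of 10. The interval of its ratio, 0.60 to 1.44, was wide because the counts behind it were 165 and 69 reads.

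**Figure D1:**
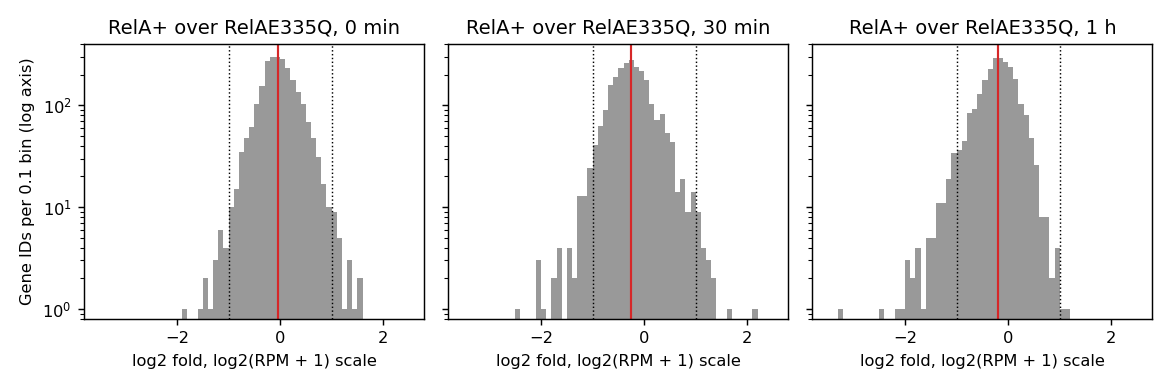
Histograms of the log2 fold of RelA+ over RelAE335Q on the log2(RPM + 1) scale at 0 min, 30 min and 1 h for 2443 gene IDs, with the number of IDs per bin on a log axis, the median as a red line and 2-fold limits as dotted lines. At 1 h 99 IDs lie beyond the lower limit and 2 beyond the upper one, against 18 and 21 before induction.

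The split between lower and higher depended on the processing in size and not in direction at 1 h, under the settings tried. With median-of-ratios scaling 52 IDs were lower and 8 higher, with equal totals 65 and 7, and with quantile normalization 40 and 12. A pseudocount of 10 gave 46 lower and 1 higher, the 99th percentile of the fold before induction as the threshold 60 and 1, and no filter 136 and 10. Subtracting the strain difference seen before induction, that is taking the change in RelA+ minus the change in RelAE335Q, gave 191 IDs at least 2-fold lower and 30 higher at 1 h. With median-of-ratios scaling these were 122 and 52. The difference of changes adds the noise of the libraries before induction. Its interquartile range was 0.676 on the log2 scale, against 0.458 for the strain fold at 1 h. Its larger counts at the same 2-fold limit are thus no sign of a larger effect. By this difference of changes, Synpcc7942_0891 was at -3.29, Synpcc7942_2300 at -2.46, Synpcc7942_2529 at 1.48 and Synpcc7942_0746 at 0.98 on the log2 scale. These IDs were selected on this measure together with the strain fold at 1 h, so the values are no separate check.

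At 30 min the comparison asked what the active enzyme had changed early. As deposited, 67 IDs were at least 2-fold lower in RelA+ and 20 higher. This direction turned with the scaling: 22 lower and 55 higher with median-of-ratios scaling, 30 and 43 with equal totals, and 21 and 47 with quantile normalization. Of the 20 higher IDs, 7 were R-numbered. Synpcc7942_2300 was already 3.23-fold lower, at 77.3 against 252 RPM (log2 -1.69, interval of the ratio -1.82 to -1.59). Synpcc7942_2529 was 1.94-fold higher, at 6490.0 against 3341 RPM. Synpcc7942_0891, at 26.4 against 37.3 RPM, was at a log2 fold of -0.48, or -0.23 with median-of-ratios scaling and -0.18 with quantile normalization. The difference of changes gave 140 IDs lower and 52 higher at 30 min as deposited, 93 and 61 with equal totals, 65 and 87 with median-of-ratios scaling and 65 and 93 with quantile normalization. Of the 52 higher IDs as deposited 25 were R-numbered, and 27 were left without that class. The median of the 32 tested R-numbered IDs was 1.33 as deposited, 1.56 with median-of-ratios scaling and 1.42 with quantile normalization. This class thus adds to the higher IDs under those scalings too, and counts without it are not given for them. From the deposited values, the difference of changes had 57 lower and 31 higher with a pseudocount of 10. At the 99th percentile threshold it had 86 and 35.

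Before induction the strains differed at fewer genes as deposited: 18 IDs were at least 2-fold lower and 21 higher in RelA+. The gap to 1 h was smaller under the other scalings. With median-of-ratios scaling 15 IDs were lower and 22 higher before induction, against 52 and 8 at 1 h. With equal totals the counts were 14 and 29, against 65 and 7. With quantile normalization they were 19 and 23, against 40 and 12. As deposited, the log2 folds before induction ran from -1.90 to 1.57, and 99% lay within 1.13 of no change. This pair of libraries gives one measure of how far cultures differ without the inducer, though from a single pair. In 100 draws with counting error alone, no ID came out 2-fold apart in any comparison between libraries.

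The change over time in the RelAE335Q strain holds the inducer, the hour of sampling and the passing of subjective dusk without active RelA. In that strain 60 IDs were at least 2-fold lower and 18 higher at 30 min, and 101 lower and 20 higher at 1 h. With median-of-ratios scaling the 1 h split was 59 lower and 49 higher, with equal totals 69 and 38, and with quantile normalization it turned to 51 lower and 57 higher. The strongest decrease was to a log2 change of -4.65 and the strongest increase to 3.66 at 1 h.

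In the RelA+ strain 132 IDs were lower and 21 higher at 30 min, and 288 lower and 12 higher at 1 h. With median-of-ratios scaling the splits were 75 lower and 32 higher at 30 min and 103 lower and 39 higher at 1 h. With quantile normalization they were 63 and 37, then 94 and 38. Both strains shared part of these changes. At 30 min 33 IDs were lower in both strains, where independent lists of these sizes would share 3.24, and 7 were higher in both, against 0.155. At 1 h 58 were lower in both, against 11.9, and 5 higher, against 0.0982. Across genes, which are not independent replicates, the 1 h changes of the strains correlated with r = 0.445 and rho = 0.274.

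The same genes tended to stand apart at both induced times, weakly. Across the 2443 IDs the fold of RelA+ over RelAE335Q at 30 min correlated with that at 1 h with r = 0.217 (95% bootstrap interval over genes 0.165 to 0.270) and rho = 0.262. These comparisons share no library. The fold before induction correlated with that at 30 min with r = 0.149 (interval 0.101 to 0.196). With the fold at 1 h it gave r = -0.058 (interval -0.107 to -0.008). These intervals resample genes as if independent, although consecutively numbered IDs differed together, and they cover no variation between cultures. An interval that leaves out 0 is thus no test of a relation between the folds. Of the IDs at least 2-fold lower, 19 were lower at both induced times, where independent lists would share 2.72, and no ID was higher at both. With median-of-ratios scaling 8 were lower at both, against 0.468, and 3 were higher at both, against 0.180. As deposited, the lists before induction and at 30 min shared 2 lower IDs, against 0.494, and 1 higher, against 0.172. Those before induction and at 1 h shared 2 lower IDs, against 0.729, and no higher ID. An excess over independent lists was thus not limited to the induced times.

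Loci for the stringent response were fixed by locus tag before the data were examined. The pairing of tag and gene for these and for the clock genes comes from general knowledge of this organism, not from a table used here. The induced relA copy is not analysed here. The resident rel gene (Synpcc7942_1377), which encodes the (p)ppGpp synthetase and hydrolase homolog, had log2 folds of RelA+ over RelAE335Q of -0.09, -0.10 and -0.07 at the 3 times, which turned to 0.16 and 0.12 at 30 min and 1 h with median-of-ratios scaling. It stood at 697, 565 and 562 RPM in RelA+ at 0 min, 30 min and 1 h, and at 743, 605 and 592 RPM in RelAE335Q. The difference of changes was -0.01 at 30 min (interval -0.08 to 0.06) and 0.02 at 1 h (interval -0.05 to 0.09) on the log2 scale. With median-of-ratios scaling these values were 0.23 and 0.19, outside those intervals. The hibernation promoting factor gene hpf (Synpcc7942_2352), whose product holds ribosomes in an inactive paired form, was at 968, 1494 and 1193.0 RPM in RelA+ and at 899, 1092 and 1207 RPM in RelAE335Q. Its log2 change at 30 min was 0.63 with the active enzyme and 0.28 with the inactive one, a difference of 0.35 (interval 0.29 to 0.40), or 0.58 with median-of-ratios scaling. At 1 h the changes were 0.30 and 0.42, a difference of -0.12 (interval -0.18 to -0.07) that turned to 0.05 with median-of-ratios scaling. No fold of rel or hpf reached 2.

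**Figure D2:**
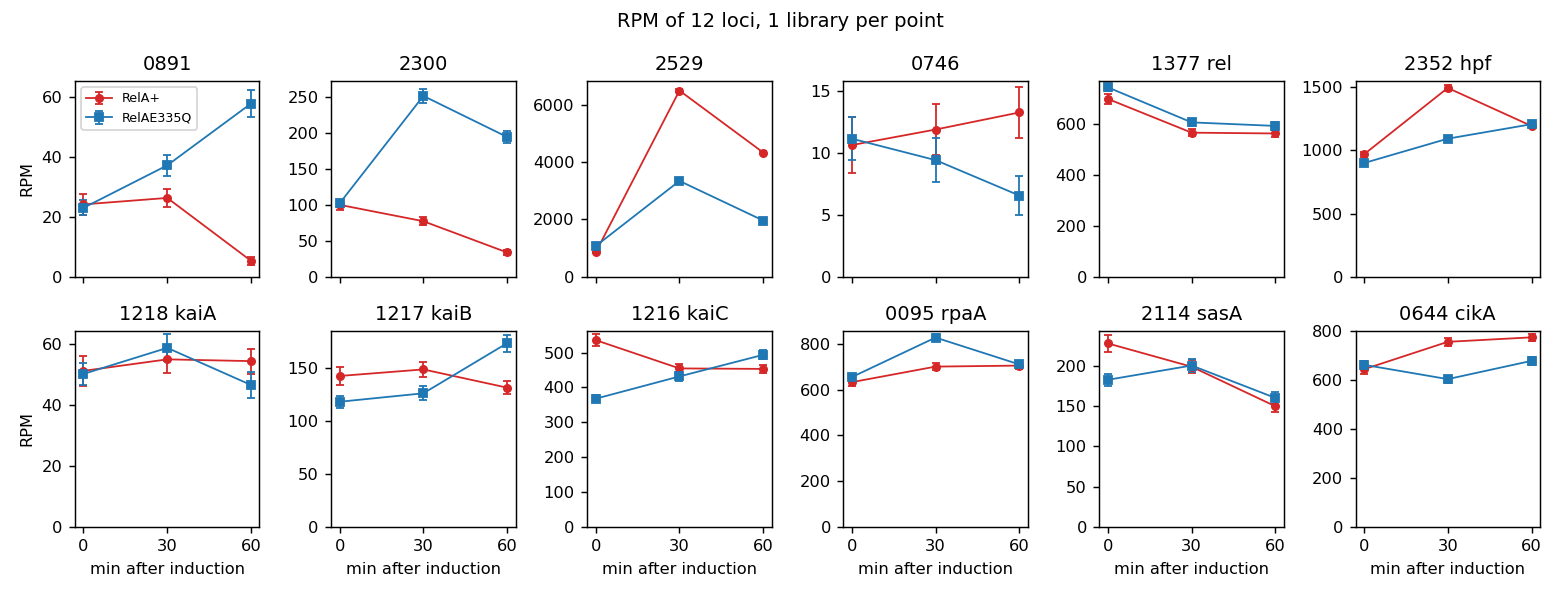
RPM of 12 loci against minutes after induction, RelA+ in red and RelAE335Q in blue, 1 library per point, bars for 95% counting intervals, each panel with its own axis from 0. Synpcc7942_2300 is at 33.8 RPM in RelA+ and 195 RPM in RelAE335Q at the last time, while rel is at 562 and 592 RPM.

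The circadian clock genes form the only fixed list with members in this file. Its 6 members were the oscillator genes kaiA (Synpcc7942_1218), kaiB (Synpcc7942_1217) and kaiC (Synpcc7942_1216), with rpaA (Synpcc7942_0095), sasA (Synpcc7942_2114) and cikA (Synpcc7942_0644). None of them differed 2-fold in any of the 9 comparisons. The median log2 fold of the list in RelA+ over RelAE335Q was 0.15 at 0 min, 0.03 at 30 min and -0.05 at 1 h. Among 10000 random lists of the same size matched on mean expression it was at the 92.7th, 93.0th and 80.9th percentile in this order. At 1 h the median turned to 0.14 with median-of-ratios scaling. The changes at 30 min and 1 h were at the 91.7th and 94.3rd percentile in RelA+ and the 89.0th and 95.2nd in RelAE335Q. The list thus stood high before induction and with either enzyme. The difference of changes at 30 min was at the 55.2nd percentile. The median of the difference of changes at 1 h was -0.19, at the 35.6th percentile, and -0.01 with median-of-ratios scaling.

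Among the oscillator genes, kaiB and kaiC had the largest differences of changes at 1 h, under the main scaling and the 3 others. The kaiC transcript was at 536, 454 and 453 RPM in RelA+ and at 367, 431 and 493 RPM in RelAE335Q. Its difference of changes was -0.67 at 1 h (interval -0.75 to -0.59), or -0.49 with median-of-ratios scaling, and most of it came from the higher level in RelA+ before induction (log2 0.54). The kaiB transcript was at 143, 149 and 132 RPM in RelA+ and at 118, 126 and 174 RPM in RelAE335Q, a difference of changes of -0.67 (interval -0.82 to -0.52) at 1 h, or -0.49 with median-of-ratios scaling. The kaiA values, 54.2 and 46.4 RPM at 1 h, gave a difference of changes of 0.19 whose interval, -0.05 to 0.44, included no change; with median-of-ratios scaling the difference was 0.36 and with quantile normalization 0.39. The cikA transcript was at 775 RPM in RelA+ and 678 RPM in RelAE335Q at 1 h, with a log2 fold of 0.19, or 0.39 with median-of-ratios scaling. The sasA transcript was at 150 and 160 RPM with changes since 0 min of -0.60 and -0.19, which became -0.20 and 0.04 with median-of-ratios scaling. The rpaA transcript was at 705 and 711 RPM at 1 h.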

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

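The pre-induction pair as a test, the thinning to equal library totals, the counting draws as a test and the test of recovery by library were chosen only after the results were seen. Median-of-ratios scaling itself was chosen before the data were examined, but the bound that decides the scaling tests was set after the result was seen.

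At 3 of the 12 loci the change after induction went one way in RelA+ and the other way in RelAE335Q at both times; with 1 library per group this difference was not tested. The first 2 of these loci were selected for their strain difference and difference of changes at 1 h, which favours opposite changes, so the tally is no evidence of how common such changes are. Synpcc7942_2300 had log2 changes of -0.37 and -1.54 in RelA+ against 1.29 and 0.92 in RelAE335Q at 30 min and 1 h, a difference of changes of -2.46 at 1 h. Synpcc7942_0746 had changes of 0.15 and 0.29 against -0.22 and -0.69, a difference of 0.98 at 1 h, and the counting intervals of both RelA+ changes and of the RelAE335Q change at 30 min include no change. The kaiC transcript (Synpcc7942_1216) had changes of -0.24 and -0.24 against 0.23 and 0.42, a difference of -0.67 at 1 h, but its RelA+ changes were 0.00 and 0.17 with median-of-ratios scaling.

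More IDs were 2-fold lower than higher with the active enzyme at both induced times. At 30 min the authors' scaling may account for this, since median-of-ratios scaling gave 0.4 lower IDs per higher one. That scaling sets the typical fold near 0 by construction, so it would also remove a real fall across most transcripts. The turn at 30 min therefore cannot tell the authors' scaling from such a fall. At 1 h the counts argue against scaling as the whole cause, with 6.5 lower IDs per higher one after median-of-ratios scaling. In each of 100 draws with counting error alone 0 IDs were lower, against 99 observed. The draws also gave 0 before induction, where 18 were observed. They leave out differences between cultures, so they do not bear on 1 h in particular. Thinning to equal library totals gave 108 lower IDs per higher one, a ratio that rests on 1 higher ID. Thinning keeps the expected share of reads of each ID, so it could hardly turn the split and does not decide on depth. A library at 1 h that differed for reasons other than the enzyme cannot be told apart from an effect of active RelA, because each strain and time has 1 library; the pair before induction, at 0.857 lower IDs per higher one, is a single pair. Lower transcript levels after 1 h of active RelA thus stay a hypothesis, which replicate cultures of each strain and time would test.

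The R-numbered IDs moved together and changed sign between the strains with time. Their median log2 fold of RelA+ over RelAE335Q over 32 IDs was -0.59 at 0 min, 0.74 at 30 min and -0.75 at 1 h, with the same signs under each of the 3 other scalings, and at least 87.5% of them went with the class median in each of these comparisons. Recovery of these RNAs that varied from library to library may explain this, but a change of their level in the cells would look alike, so the explanations cannot be told apart. Swapped 30 min and 1 h labels in 1 strain also stay open: across the other 2411 IDs the steps from 30 min to 1 h in the strains correlated with r = 0.0854 (95% bootstrap interval over genes 0.033 to 0.132) and rho = 0.116. This lies above the bound of -0.1 set for a swap, which argues against one, but r does not pass the bound of 0.1 set for excluding it.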

How the results depend on the processing

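Leaving out the R-numbered IDs and thinning were chosen after the data were seen; the cause of the shifts below was not tested, except that no filter and the stricter filter change the IDs tested. Of the counts, 91 stayed within 1.5 times the main count and 73 did not. Of single-locus values, 122 were counted as unmoved relative to their counting intervals and 70 as moved. The unmoved ones include values outside the interval printed here for the ratio without a pseudocount. Synpcc7942_0891 in RelA+ over RelAE335Q at 1 h was so counted at -3.06 with median-of-ratios scaling, against -3.84 to -3.08. The tally of 122 and 70 is no measure of stability, since changing the filter could not alter the value of a locus. The leading IDs, selected for large values, kept their sign at 1 h under the 3 other scalings. In RelA+ over RelAE335Q at 1 h, rel, hpf, kaiC, rpaA and sasA turned from below 0 to above 0 with median-of-ratios scaling. Median-of-ratios scaling brings the median of all IDs near 0 by construction. In RelA+ over RelAE335Q that median went from -0.25 to 0.00 at 30 min and from -0.19 to 0.00 at 1 h. Directions of small folds are thus relative to the scaling. A comparison of the strains over the 3 times with time as a block was not run. All 6 clock genes passed the filter, so the choice of members could not move that list. Depth limits low genes: Synpcc7942_0746 rests on 69 reads in the RelAE335Q library at 1 h.

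With median-of-ratios scaling, RelA+ over RelAE335Q had 55 higher and 22 lower at 30 min and 8 higher and 52 lower at 1 h; RelA+ over its start had 32 higher and 75 lower at 30 min and 39 higher and 103 lower at 1 h. RelAE335Q over its start had 49 higher and 59 lower at 1 h, and the difference of changes 87 higher and 65 lower at 30 min and 52 higher and 122 lower at 1 h. With quantile normalization the same counts, in this order, were 47 and 21, 12 and 40, 37 and 63, 38 and 94, 57 and 51, 93 and 65, and 64 and 109. With equal totals without R-numbered IDs, RelA+ over RelAE335Q had 43 higher and 30 lower at 30 min and 7 higher and 65 lower at 1 h, RelA+ at 1 h had 191 lower, RelAE335Q at 1 h 38 higher, and the difference of changes at 30 min 93 lower.

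With no filter, RelA+ over RelAE335Q had 40 higher and 38 lower at 0 min and 10 higher at 1 h, RelA+ had 35 higher at 30 min and 21 at 1 h, RelAE335Q 31 higher at 30 min, and the difference of changes 80 higher at 30 min and 54 at 1 h. With the stricter filter, RelA+ over RelAE335Q had 9 lower at 0 min and 1 higher at 1 h, and the difference of changes 11 higher at 1 h. With a pseudocount of 10, RelA+ over RelAE335Q had 8 higher and 7 lower at 0 min, 11 and 22 at 30 min, and 1 and 46 at 1 h; RelA+ had 69 lower at 30 min and 155 at 1 h. RelAE335Q then had 11 higher at 30 min and 12 higher and 49 lower at 1 h, and the difference of changes 31 higher and 57 lower at 30 min and 9 higher and 97 lower at 1 h. A pseudocount of 0.1 moved no count by over 1.5 times.

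At the 99th percentile threshold, RelA+ over RelAE335Q had 12 higher at 0 min, 10 higher and 41 lower at 30 min, and 1 higher and 60 lower at 1 h, RelAE335Q had 11 higher at 30 min and 12 at 1 h, and the difference of changes 86 lower at 30 min and 19 higher at 1 h. After thinning to the shallowest library 1 ID was higher at 1 h. Without R-numbered IDs, 13 IDs were higher in RelA+ over RelAE335Q at 30 min and 27 in the difference of changes at 30 min. The correlation of the strain fold at 30 min with that at 1 h was then 0.279. That of 0 min with 30 min also rose, to 0.207, and that of 0 min with 1 h was -0.103.

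The clock median stayed within its counting interval in 51 cases and left it in 21. This tally is no measure of stability, since changing the filter could not move the list. The cases that left the interval came from the 3 other scalings, apart from the mean given last. With median-of-ratios scaling the clock median was 0.29 at 30 min and 0.14 at 1 h in RelA+ over RelAE335Q, 0.32 and 0.39 in RelA+ over its start, 0.31 in RelAE335Q at 1 h, and 0.0755 and -0.0139 in the difference of changes. With quantile normalization the same medians were 0.21, 0.0922, 0.27, 0.39, 0.23, 0.0299 and -0.0195. With equal totals it was 0.24, 0.22 and 0.0689 in RelA+ over RelAE335Q at the 3 times, 0.16 in RelA+ and 0.22 in RelAE335Q at 1 h, and -0.0558 in the difference of changes at 30 min. The mean in place of the median gave 0.14 in RelAE335Q at 1 h.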

Other observations

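A pair of B-numbered IDs was at least 2-fold higher in both strains after induction, and no other tested ID of that class was. The summed share of the 19 B-numbered IDs was 2.39-fold its starting value at 30 min and 2.25-fold at 1 h in RelA+, and 2.72-fold and 2.28-fold in RelAE335Q. The same 2 of these IDs were at least 2-fold higher each time and held 62.2% to 68.4% of the sum, while the sum of the others was 0.952-fold and 0.864-fold in RelA+ and 1.02-fold at both times in RelAE335Q. The class median of the log2 change was -0.35 and -0.16 in RelA+ and 0.06 and -0.26 in RelAE335Q at 30 min and 1 h. With median-of-ratios scaling these were -0.11 and 0.23 in RelA+ and 0.06 and -0.02 in RelAE335Q. Between the strains, the median of the class in RelA+ over RelAE335Q was 0.16 at 0 min, -0.05 at 30 min and -0.04 at 1 h, and the latter 2 values turned to 0.21 and 0.14 with median-of-ratios scaling. This class was chosen after its values were seen.

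The share of reads in a few IDs differed between the libraries. The R-numbered IDs together held 24.6%, 29.1% and 28.5% of the reads in RelA+ and 25.9%, 25.6% and 28.9% in RelAE335Q at 0 min, 30 min and 1 h, mostly from Synpcc7942_R0017. Without that ID the tested R-numbered IDs held 3.48%, 4.12% and 3.08% in RelA+ and 4.54%, 3.28% and 3.63% in RelAE335Q.

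Consecutively numbered IDs differed together. In RelA+ over RelAE335Q at 1 h, the log2 folds of 2221 pairs of consecutive IDs correlated with r = 0.194, and the highest of 1000 shuffled orders gave 0.074. Errors independent from gene to gene are therefore unlikely to make up all of the spread between these libraries. The pair before induction gave r = 0.209, so this structure was present without the inducer and may reflect shared transcripts, differences between the cultures or bias along the genome; no test here separates these, and no effect of the enzyme was tested by it.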
